A study of Mus musculus with 6 samples.

How the data were processed

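Transcripts were measured in 6 samples of sorted thymic NKT cells, 3 CD103+ and 3 CD103-, each on an Illumina mouse expression array with biotin-labelled cRNA made from column-purified total RNA. The deposited intensity values are 1 fluorescence signal per probe and array, summarised over beads, without normalization and with background included, as the file headers and the differing array medians show. Beside each of them the deposited table gives another value, named a detection p-value in the file headers. It was taken as that of the signal against the negative controls of the same array. A second table holds log2 values made by the authors, background-adjusted and scaled between arrays by a method not given in the sources used here. In that table the order of probes within an array was that of the signal, and the slope against log2 signal at the bright end was 1.02 to 1.07. Its column medians were 5.20, 5.18 and 5.21 for CD103+ and 5.21, 5.42 and 5.42 for CD103-, so the arrays were not brought to 1 median, and which scaling was applied stays unknown.

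Of 45281 probes in the signal table, 18 whose values were shifted by annotation text inside the line were left out, which left 45263. Probes were named by gene symbol from an annotation of the array and a mouse gene table. A single symbol was found for 34874 probes, several for 18 and none for 10371. Probes without a single symbol stayed in the tests and were not named. Signals were background-corrected, quantile-normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and the background inferred from the detection p-values. Probes with a detection p under 0.05 on at least 3 of 6 arrays were kept, which left 17462 probes and 8999 genes. Arrays were grouped by their labels, and CD103+ minus CD103- was tested with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05 on the adjusted p. The median SE was 0.195 log2 units with 7.34 total degrees of freedom. With 3 arrays against 3, an exact permutation test of a single gene could not go below 0.1.

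A gene was represented by its kept probe with the highest mean over all arrays. A gene whose probe was not detected on any array of a population was given as a bound, the fold of that probe against the higher, per array, of its own signal and the lowest normalized signal among detected probes. For named genes past the threshold that were detected on part of these arrays, the value is also given with the undetected arrays at the latter signal. Gene lists with at least 3 measured members were tested against all other genes with camera of limma at a preset correlation of 0.01, two-sided, adjusted over 33 lists. An estimated correlation left 0 of the 7 lists past the threshold, with 5 lists at an unadjusted p under 0.05, and the rotation test fry, which asks whether the genes of a list move 1 way on balance, gave 15. Median differences of lists are also given with undetected members at their bound. The named genes were 12 sort and identity genes given in every case, up to 14 genes in each direction with the largest log2 difference among those past the threshold with separated groups, and up to 4 members past the threshold from each list, with 59 genes in all, of which 49 passed. Of the 12 genes and of the 35 lists, 1 each is not reported here. The design, the 35 lists, the rule for named genes and all alternatives not named below as later were chosen before the data were examined.

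The labels state no pairing of replicate numbers across the populations. It was checked by correlating, over kept probes, each array's deviations from its population mean with those of the other population. Arrays of the same number gave 0.170, 0.125 and 0.305, and arrays of different numbers -0.231 to 0.0824, with each array correlating best with its own number. With so few arrays this match could arise by chance. The correlations are also not independent of each other, since deviations were taken from the population means. The data therefore leave open whether the numbers pair the arrays. The main fit took the arrays as unpaired, and a fit with the replicate number as a block is given beside the results it changes.

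The alternatives tried were no background correction, normexp without detection p-values, median scaling, cyclic loess, an offset of 50, the authors' values, no filter, a filter at a detection p under 0.01 on all 3 arrays of a population, an intensity trend with robust eBayes, array weights, the replicate block, leaving out each array in turn, an adjusted p of 0.01, a minimum log2 difference of 1, the estimated correlation, fry and all kept probes of each member. Chosen after seeing the data were the bright arrays alone (CD103+ arrays 1, 2 and 3 against CD103- array 1), array brightness as a covariate, and median scaling and the authors' values centred on the median of all kept probes. Before centring that median was -0.14 with median scaling and 0.13 in the authors' values, against 0.04 with the main normalization. The fit was tested on simulated data with 17462 probes and the same numbers of arrays. It recovered 40% of 100 probes with a log2 change of 1 and 89% of 100 with a change of 2, 3.01% of its calls were of unchanged probes, and 2.51% of 199 unchanged lists had a p under 0.05. The simulated probes varied independently, with the same spread on every array. The simulation therefore cannot show how the list test behaves with correlated members or dim arrays. Among the lists past the threshold the estimated correlation reached 0.142. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.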

Results

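Gene expression was measured on Illumina bead arrays in mature NKT cells of the mouse thymus. NKT cells are T lymphocytes whose invariant receptor recognises lipids presented by CD1d. Cells positive for CD44 and NK1.1 were sorted from male mice of the C57BL/6 strain into a population with CD103 at the surface and one without it. Each population was measured on 3 arrays, given as biological replicates in the series design, and no other group was measured. The series concerns DOCK8, a regulator of the actin cytoskeleton, and the survival and function of NKT cells. The comparison asks how the transcripts of CD103+ thymic NKT cells differ from those of CD103- thymic NKT cells.

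The arrays differed in brightness. The mean signal over 45263 probes was 612.7, 825.9 and 501.6 on CD103+ arrays 1, 2 and 3. It was 526.2, 277.4 and 276.5 on CD103- arrays 1, 2 and 3. Between 38.3% and 40.5% of probes were detected on the CD103+ arrays, and 38.8%, 34.0% and 35.2% on CD103- arrays 1, 2 and 3. Pearson correlations of log2 signals between arrays, taken across probes, which are not independent replicates, were 0.984 to 0.990 within CD103+ and 0.964 to 0.967 within CD103-. CD103- array 1 correlated with the CD103+ arrays at 0.972 to 0.976, above its values of 0.964 and 0.966 with CD103- arrays 2 and 3. The first principal component held 44.4% of the variance and parted CD103- arrays 2 and 3, at 41.6 and 40.0, from the other 4 arrays, with CD103- array 1 at -2.80 and the CD103+ arrays at -31.1 to -19.0. The second held 23.0%. The number of arrays limits the precision of every value.

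**Figure D1:**
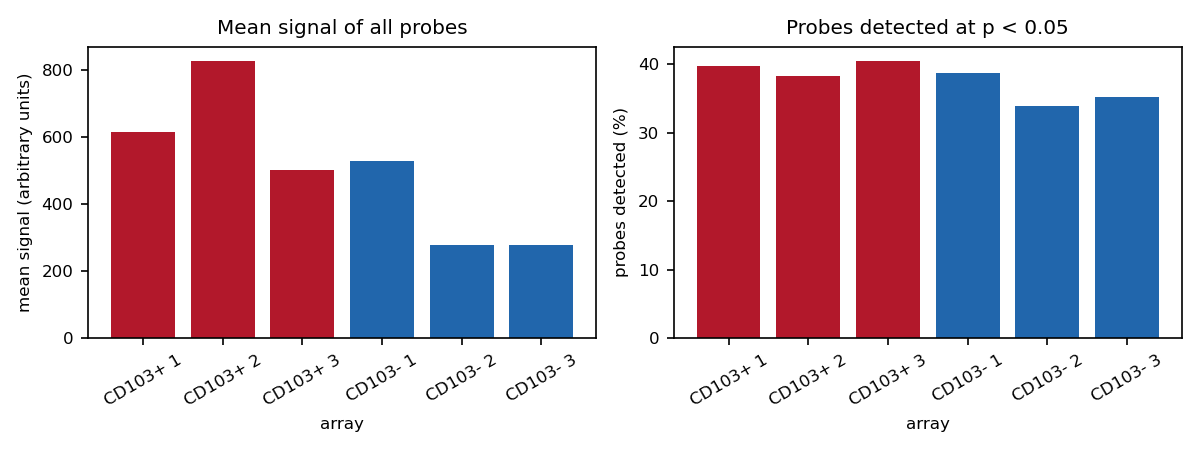
Mean signal of all probes in arbitrary units (left) and percent of probes with a detection p-value under 0.05 (right) on each of the 6 arrays, with CD103+ arrays in red and CD103- arrays in blue. CD103- arrays 2 and 3 had mean signals of 277.4 and 276.5, below the other 4 arrays.

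The sorted CD103+ population had more transcripts of the lysozyme genes Lyz2 and Lyz1, of the complement genes C1qb and C1qc, of the Src family kinase Blk, of the lectin-like receptors Klrh1 and Klri2, of the adhesion molecule E-cadherin (Cdh1) and of the cytokine Il2. It had less Gimap7, a GTPase of lymphocytes, less Slamf6 and Slamf1, receptors that take part in NKT cell development, and less Csf2, the cytokine GM-CSF. The lysozyme and complement genes are also macrophage genes, and 17 of 32 measured genes of a macrophage list written after the values were seen were higher (11 with the replicate number as a block). With the replicate number as a block Lyz1, Slamf6, Slamf1 and Csf2 did not pass, at adjusted p of 0.0604 (1.52e-04 to 0.290 over 21 alternatives), 0.0546 (0.00404 to 0.218), 0.0565 (0.00700 to 0.365) and 0.0752 (0.0144 to 0.218). Klri2 was 5.34-fold higher (log2 difference 2.42, SE 0.209, n = 3 per group, adjusted p = 0.00453), Cdh1 4.31-fold (2.11, SE 0.201, adjusted p = 0.00528) and Il2 3.48-fold (1.80, SE 0.183, adjusted p = 0.00693). Gimap7 was 4.35-fold lower (log2 difference -2.12, SE 0.234, adjusted p = 0.00914). Dock8 itself did not pass the test (log2 difference -0.17, SE 0.169, adjusted p = 0.680), and a second Dock8 probe lay at 0.16.

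Itgae, which encodes the CD103 chain used for the sort, was 26.5-fold higher in CD103+ cells, with log2 signals of 13.60 ± 0.19 against 8.87 ± 0.24 (SD, n = 3) and an adjusted p of 9.5e-05. All 6 Itgae probes passed, with log2 differences of 3.76 to 5.15. Its partner chain Itgb7 had a log2 difference of 0.34 (adjusted p = 0.372). The other sort and identity genes did not pass either, with values of -0.46 for Klrb1c, which encodes NK1.1 (adjusted p = 0.332), and -0.10 for Cd44 (adjusted p = 0.794).

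Of 17462 probes tested, 206 passed an adjusted p of 0.05, 162 higher and 44 lower in CD103+ cells, so 78.6% of them were higher. By the brightest probe of each gene, 104 genes were higher and 20 lower of 8999 measured. In all 206 probes the 3 arrays of one population lay beyond the 3 of the other, as did 21.9% of tested probes, where chance gives 10%. Of the 162 higher probes, 76 were not detected on any CD103- array, while of the 44 lower probes 1 was not detected on any CD103+ array. Such probes passed the detection filter through the 3 arrays of 1 population, and fewer probes were detected on the dim CD103- arrays. How far this sets the share of higher probes was not tested. The count was 135, with 87 shared, when the dim CD103- arrays were left out, 83, with 82 shared, when the replicate number was a block, and 16 with array brightness as a covariate, while median scaling gave 65 higher and 83 lower. Without CD103+ array 1, 2 or 3 the count was 52, 59 or 54, and without CD103- array 1, 2 or 3 it was 857, 120 or 114; of the 49 named genes that passed, 28, 27, 28, 0, 16 and 14 no longer did in these fits, 22 no longer did with the block, 18 with the dim arrays left out and 43 with array brightness as a covariate.

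Among the 14 named genes with the largest increase, 7 were not detected on any CD103- array. For such genes the fold is a lower bound, taken against the lowest normalized signal of a detected probe. C1qb was at least 7.97-fold higher in CD103+ cells (adjusted p = 0.00255), Vcam1, an adhesion molecule, at least 8.73-fold (adjusted p = 0.00521), and Blk at least 7.37-fold on the brightest of its 3 probes, all of which passed (adjusted p = 6.23e-04). The lipid carrier Apoe was at least 6.33-fold higher (adjusted p = 0.00521), C1qc at least 5.63-fold (adjusted p = 0.00537), Ear3, a ribonuclease of the eosinophil-associated family, at least 5.19-fold (adjusted p = 0.00255), and the inhibitory receptor Sirpa at least 4.12-fold (adjusted p = 0.00520). Lyz2, detected on 2 CD103- arrays, was 31.7-fold higher (log2 difference 4.98, SE 0.324, adjusted p = 0.00119) and Lyz1 21.3-fold (4.41, SE 0.523, adjusted p = 0.0118). The interferon-inducible membrane protein Ifitm2 was 11.6-fold higher (3.53, SE 0.198, adjusted p = 6.23e-04), and Klrh1, Slc40a1, the iron exporter ferroportin, and Niban2, each detected on 1 CD103- array, were higher with adjusted p of 0.00460, 0.0136 and 0.00521. With undetected arrays at their lowest detected signal, Lyz2 was 24.5-fold, Klrh1 5.17-fold, Slc40a1 9.99-fold and Niban2 8.12-fold higher. With the replicate number as a block, Lyz1 did not pass, nor did Slc40a1 (adjusted p = 0.0668, 5.55e-04 to 0.121 over 21 alternatives).

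**Figure D2:**
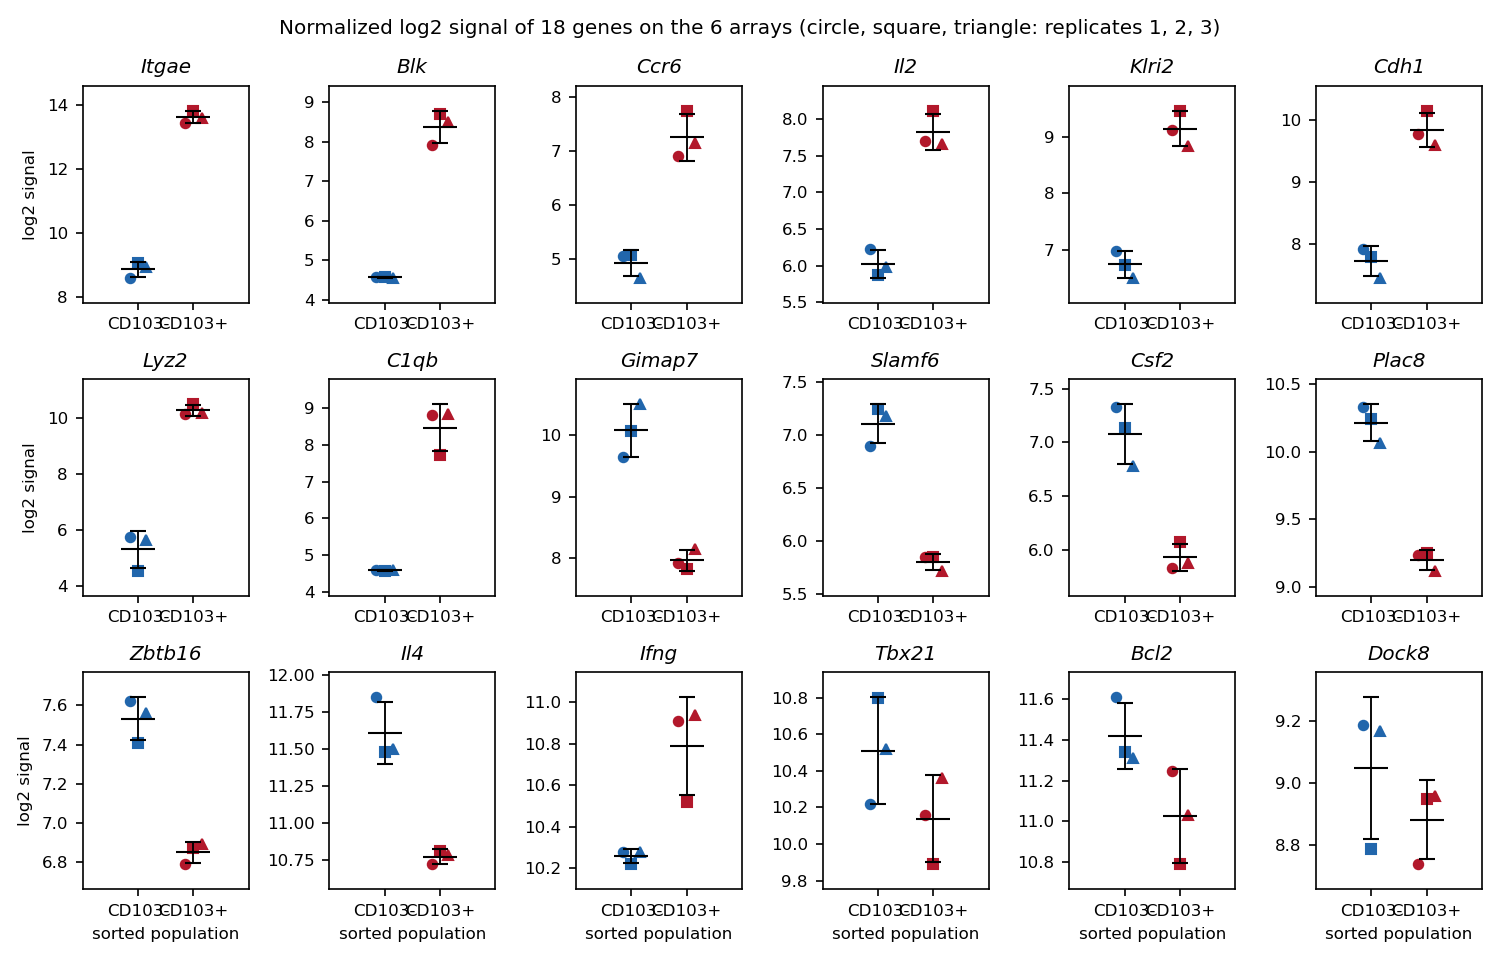
Normalized log2 signal of 18 genes on each array, with CD103- in blue and CD103+ in red; circles, squares and triangles are replicates 1, 2 and 3, and bars give the mean and SD of 3 arrays. Itgae had means of 8.87 and 13.60, and Zbtb16, Il4, Ifng, Tbx21, Bcl2 and Dock8 did not pass an adjusted p of 0.05.

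The 14 named genes with the largest decrease were 2.06-fold to 4.35-fold lower, and 13 of them were detected on all 6 arrays. After Gimap7 came Tmem273 (log2 difference -1.59, or -1.58 with an undetected array at its lowest detected signal, adjusted p = 0.00521), Asb2, a substrate-binding subunit of a ubiquitin ligase (-1.54, adjusted p = 0.00945), and the protease inhibitor Serpina3f (-1.49, adjusted p = 0.00521). These 4 genes also passed with the replicate number as a block. The other 10 did not, with adjusted p from 0.0546 to 0.116 in that fit (8.05e-04 to 0.544 over their 21 alternatives each) after 0.0111 to 0.0440 without the block. They were the histone kinase Haspin (-1.34), Slamf6 (-1.31), Slamf1 (-1.23), the repressor Hic1 (-1.23), the DNA repair enzyme Alkbh2 (-1.15), Csf2 (-1.15), the proteoglycan Gpc1 (-1.07), the death receptor Tnfrsf25 (-1.06), Baz2a (-1.04) and Sv2a (-1.04). A second probe did not pass for Slamf6 (0.03), Tnfrsf25 (-0.16), Sv2a (-0.23) and, not detected on any CD103+ array, Slamf1 (bound 1.39-fold lower).

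Markers of myeloid and dendritic cells were higher in CD103+ cells. Of 11 measured members 6 were higher and none was lower, also when adjusted over the list alone, and the list had a median log2 difference of 1.71 (1.33 with 3 undetected members at their bound, adjusted p = 1.99e-06). With an estimated correlation the adjusted p was 0.173, the highest of 24 alternatives, which began at 1.00e-10. Beside Lyz2 and Lyz1, the higher members were the pore-forming protein Mpeg1 (2.54, or 2.33 with an undetected array at its lowest detected signal, adjusted p = 0.0223) and the macrophage receptor Adgre1 (at least 2.59-fold, adjusted p = 0.00537), with Fcgr3 and Ctsh at least 2.51-fold and 2.36-fold higher (adjusted p = 0.0143 and 0.0273). With the replicate block the adjusted p was 0.0885 for Mpeg1 (0.00116 to 0.408 over 21 alternatives) and 0.0515 for Fcgr3 (0.00666 to 0.256). Csf1r (0.31) and Cst3 (0.21) did not pass. On a list of 43 resident macrophage genes, written after the values were seen, 17 of 32 measured members were higher, among them 7 of the 14 genes with the largest increase, while 11 were with the replicate block and 9 without CD103+ array 1 or 3. Of these 17 genes, 15 lay lower on CD103+ array 2 than on the mean of CD103+ arrays 1 and 3, such as C1qb at 7.74 against 8.83 and 8.86. Lyz2 and Mpeg1 lay higher there, as did Lyz1, which is not on this list.

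In the NKT17 programme, the program of IL-17-producing NKT cells, of 10 measured members 4 were higher and none was lower, while 6 were higher and 1 lower adjusted over the list alone. The measured part of the list was higher in CD103+ cells: the median log2 difference was 1.09 (0.53 with 5 undetected members at their bound, adjusted p = 7.41e-06), and with an estimated correlation the adjusted p was 0.173 (1.33e-09 to 0.173 over 24 alternatives). Those 5 members passed the detection filter only through the 3 CD103+ arrays. Of the 17 genes fixed for the list, the cytokine genes Il17a and Il17f were among those not measured. Beside Blk, the chemokine receptor Ccr6 was at least 3.42-fold higher (adjusted p = 0.00808) on a probe detected on no CD103- array, while its other probe did not pass at 0.99. Il17re, a receptor subunit for IL-17C, was at least 1.57-fold higher (adjusted p = 0.0166) and Tmem176a at least 1.38-fold (adjusted p = 0.0424), while another Il17re probe did not pass (bound 1.35-fold). Il1r1, not detected on any CD103- array (bound 1.44-fold, adjusted p = 0.0632), and Rora, at -0.75, did not pass. Markers of gamma delta T cells, which share Blk with this list, were higher in 2 of 5 measured members and lower in none (4 higher and none lower adjusted over the list alone), with a median of 0.99 (0.56 with 2 members at their bound, adjusted p = 1.27e-04). With an estimated correlation the adjusted p was 0.197 (8.83e-08 to 0.197 over 24 alternatives). Sox13, a transcription factor of gamma delta T cells, was at least 1.47-fold higher (adjusted p = 0.0136), and Trgv4 had a log2 difference of 0.38 (adjusted p = 0.263). After median scaling centred on all probes the adjusted p was 0.0904 for both lists. With the replicate block the adjusted p was 0.0573 for Il17re (0.00884 to 0.387 over 21 alternatives, passing in 10), 0.0950 for Tmem176a (0.0332 to 0.805 over 20, passing in 2) and 0.0522 for Sox13 (0.00709 to 0.527 over 21, passing in 12).

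NK receptors were higher in CD103+ cells, with 6 of 20 measured members higher and none lower (7 higher and none lower adjusted over the list alone) and 16 of 20 differences positive. The list median was 0.40, also with 2 undetected members at their bound (adjusted p = 1.49e-05), and the adjusted p with an estimated correlation was 0.272 (3.68e-07 to 0.272 over 24 alternatives). Without the dim CD103- arrays the list median was 0.24. Beside Klri2, the signalling adaptor Fcer1g, also expressed by the myeloid cells whose markers were higher, was 3.03-fold higher (log2 difference 1.60, SE 0.143, adjusted p = 0.00518), and the activating receptors Cd244a (at least 2.18-fold, adjusted p = 0.0126) and Klrc2 (1.72, or 1.67 with an undetected array at its lowest detected signal, adjusted p = 0.0466) were higher. A second Cd244a probe did not pass (bound 1.21-fold). With the replicate block the adjusted p was 0.0565 for Cd244a (0.00431 to 0.225 over 21 alternatives) and 0.0630 for Klrc2 (0.00588 to 0.603). Klra1 was higher by 1.41 (adjusted p = 0.0199, and 0.0563 with the block, 1.71e-04 to 0.337). Markers of NK cells without a T cell receptor did not pass as a list (adjusted p = 0.0704, median 0.53, or 0.38 with 1 member at its bound). The list passed in 5 of 24 alternatives, with adjusted p from 2.71e-04 to 0.403. Of its 6 measured members Klri1 was at least 1.34-fold higher on a probe detected on no CD103- array (adjusted p = 0.0136, and 0.0565 with the replicate block, 0.00671 to 0.807 over 21 alternatives), and 3 were higher adjusted over the list alone. A second Klri1 probe did not pass (bound 1.31-fold, adjusted p = 0.0534).

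Effector cytokines moved in both directions. Il2 was higher and Csf2 lower among 11 measured members (2 higher and 2 lower adjusted over the list alone), and the list did not pass (median -0.13, adjusted p = 0.469). Csf2 had an adjusted p of 0.0752 with the replicate block (0.0144 to 0.218 over 21 alternatives). Il4 had a log2 difference of -0.84 (SE 0.157, adjusted p = 0.0632), and Ifng one of 0.53 (SE 0.162, adjusted p = 0.203). Il4 passed in 9 of 21 alternatives, with adjusted p from 0.00310 to 0.370. Tnf lay at -0.20 and Il13 at 0.38. Among 6 measured chemokines, Ccl5 was higher (1.23, SE 0.166, adjusted p = 0.0203) and none was lower, the same count adjusted over the list alone, and the list did not pass (adjusted p = 0.374). Of 13 cytotoxic granule and death ligand genes none passed limma's test, also adjusted over the list alone, and 3 had an unadjusted p under 0.05 (list adjusted p = 0.404).

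The NKT2 programme, genes of IL-4-producing NKT cells, was lower as a list (median log2 difference -0.14, mean -0.25, adjusted p = 0.0220). With an estimated correlation the adjusted p of the list was 0.363, with the replicate block 0.0580, without CD103+ array 3 0.0634, and without CD103- array 1 or 2 0.102 or 0.0702 (4.38e-04 to 0.363 over 24 alternatives). Of 9 measured members only Plac8 was lower over all probes (-1.01, adjusted p = 0.0233), and 3 were lower and none higher adjusted over the list alone. In the authors' values the list median was 0.03. Plac8 had an adjusted p of 0.0604 with the replicate block (0.00110 to 0.218 over 21 alternatives). Zbtb16, which encodes the NKT lineage factor PLZF, lay at -0.68 (SE 0.137, adjusted p = 0.0753), passing in 2 of 21 alternatives (0.0474 to 0.518), and Gata3 at 0.03 (adjusted p = 0.953). None of the 11 members of the NKT1 and T-bet programme passed limma's test, also adjusted over the list alone, with 2 at an unadjusted p under 0.05 (list median -0.17, adjusted p = 0.246), and Tbx21, which encodes T-bet, lay at -0.37 (adjusted p = 0.442). Of 11 early NKT and thymic precursor genes Slamf6 was lower, while 1 was higher and 1 lower adjusted over the list alone (list adjusted p = 0.251).

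Recirculation and lymph node homing genes were higher as a list, in 4 of 15 measured members with none lower (5 higher and none lower adjusted over the list alone), with a median of 0.39 (adjusted p = 1.27e-04). The adjusted p with an estimated correlation was 0.173 (1.85e-06 to 0.173 over 24 alternatives). The chemokine receptor Cx3cr1, also a receptor of macrophages, was higher by 1.99 (1.77 with an undetected array at its lowest detected signal, adjusted p = 0.00903), the calcium-binding protein S100a4 by 1.85 (adjusted p = 0.0109), Klf2, a factor that drives expression of thymic exit receptors, by 1.34 (adjusted p = 0.0199), and the filament protein Vim by 1.06 (adjusted p = 0.0244). Vim had an adjusted p of 0.0630 with the replicate block (4.84e-04 to 0.251 over 21 alternatives). Tissue residency genes did not pass as a list (median 0.22, adjusted p = 0.0668), although 15 of 24 alternatives put them past the threshold (2.47e-06 to 0.422). Of their 17 measured members Itgae, Cdh1 and Cd244a were higher and none was lower (4 higher adjusted over the list alone), with Cd69 at 0.10 and Cxcr6 at -0.43. Of 9 chemokine receptors Ccr6, Cx3cr1 and Ccr8 were higher and none lower, also adjusted over the list alone, with Ccr8 higher by 1.77 (adjusted p = 0.00786). That list did not pass (adjusted p = 0.374), and its median of -0.14 was opposite in sign to its mean of 0.56 and to its test. Of 21 integrin and adhesion genes Itgae and Cdh1 were higher and Slamf1 lower (3 higher and 1 lower adjusted over the list alone, list adjusted p = 0.537). Of 13 genes of the TGF-beta response Itgae was higher, and 2 were higher adjusted over the list alone (list adjusted p = 0.246). Itgae, the gene of the sort marker, is the largest difference (4.73) in the residency, adhesion and TGF-beta lists. The sort fixes its direction, and none of these lists was tested without it.

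Genes of survival did not pass. None of 6 anti-apoptotic and 8 pro-apoptotic genes passed limma's test over all probes or over the list alone, with 1 and 0 at an unadjusted p under 0.05 (list adjusted p = 0.468 and 0.877). Bcl2, the survival factor, lay at -0.39 (SE 0.175, adjusted p = 0.350), although 1 of its 6 probes was lower (-1.17, adjusted p = 0.0202), and Mcl1 lay at 0.18.

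B cell markers were higher as a list (median 0.78, adjusted p = 0.0396) although none of the 8 measured members passed limma's test over all probes, with 6 at an unadjusted p under 0.05, and 5 were higher and 1 lower adjusted over the list alone. The adjusted p of this list was 0.301 with an estimated correlation, 0.0856 with the replicate block, 0.226 with median scaling, 0.487 with median scaling centred on all probes, 0.0521 in the authors' values and 0.198 without a filter. It was 0.0543 without CD103+ array 1, 0.0634 without CD103+ array 3 and 0.158 without CD103- array 1 (1.61e-04 to 0.487 over 24 alternatives). The MHC class II genes H2-Aa (1.76, adjusted p = 0.0741), H2-Ab1 (0.83), H2-Eb1 (0.84) and Cd74 (1.01) are also expressed by macrophages, whose markers were higher too. Of the other members Cd79b lay at 0.72 and Cd22 at 0.57, while Ebf1 (-0.15) and Fcer2a (-0.54) were negative. Markers of conventional CD8 T cells did not pass (6 measured, adjusted p = 0.828), and their median of -0.09 was opposite in sign to their mean of 0.06 and their test. Actn1 was the one higher member (1.04, adjusted p = 0.0229), also adjusted over the list alone, with an adjusted p of 0.0752 under the replicate block (5.99e-04 to 0.283 over 21 alternatives), and Cd8b1 lay at -0.38. Of 10 markers of double positive thymocytes none passed, also adjusted over the list alone, with 1 at an unadjusted p under 0.05 (list adjusted p = 0.251). Of 10 markers of regulatory T cells none passed, with 4 at an unadjusted p under 0.05 and 2 lower adjusted over the list alone (median -0.25, list adjusted p = 0.0863). That list passed in 3 of 24 alternatives (0.00406 to 0.815). Of 10 genes of the T cell receptor complex none passed, with 2 at an unadjusted p under 0.05. Thy1 (-0.73) was lower adjusted over the list alone, and the list had an adjusted p of 0.246, passing in 4 of 24 alternatives (0.00139 to 0.572). For thymic epithelium and stroma, 2 markers were measured, Pecam1 at -1.02 and Ccl25 at 0.12, and for red blood cells Hba-a1 at 0.60, too few for a list test.

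The remaining lists held no member past limma's test over all probes, nor adjusted over the list alone except where given, and did not pass. The adjusted p was 0.404 for 19 cytokine receptors, of which 6 had an unadjusted p under 0.05 and 2 were higher and 3 lower adjusted over the list alone. It was 0.117 for 12 inhibitory and costimulatory receptors, 4 of them at an unadjusted p under 0.05. The 20 immediate early genes had an adjusted p of 0.638, with a mean of 0.07 where the median and the test were negative, and 3 at an unadjusted p under 0.05. The 21 type I interferon response genes had an adjusted p of 0.374, with a median of 0.02 where the mean and the test were negative, and 6 at an unadjusted p under 0.05. Cell cycle genes (23 measured, adjusted p = 0.828), glycolysis genes (12, adjusted p = 0.251) and oxidative phosphorylation genes (24, adjusted p = 0.828) had 0 members each at an unadjusted p under 0.05. Of 14 heat shock and stress genes 1 had an unadjusted p under 0.05 and was lower adjusted over the list alone (list adjusted p = 0.997). For the heat shock and the oxidative phosphorylation genes the median and mean were positive and the test negative. The 24 cytosolic ribosomal protein genes had a median of 0.09 (adjusted p = 0.554, 2 members at an unadjusted p under 0.05), and this median turned negative and passed under 5 other scalings, at -0.66 with median scaling, -0.35 with cyclic loess and -0.55 in the authors' values.

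**Figure D3:**
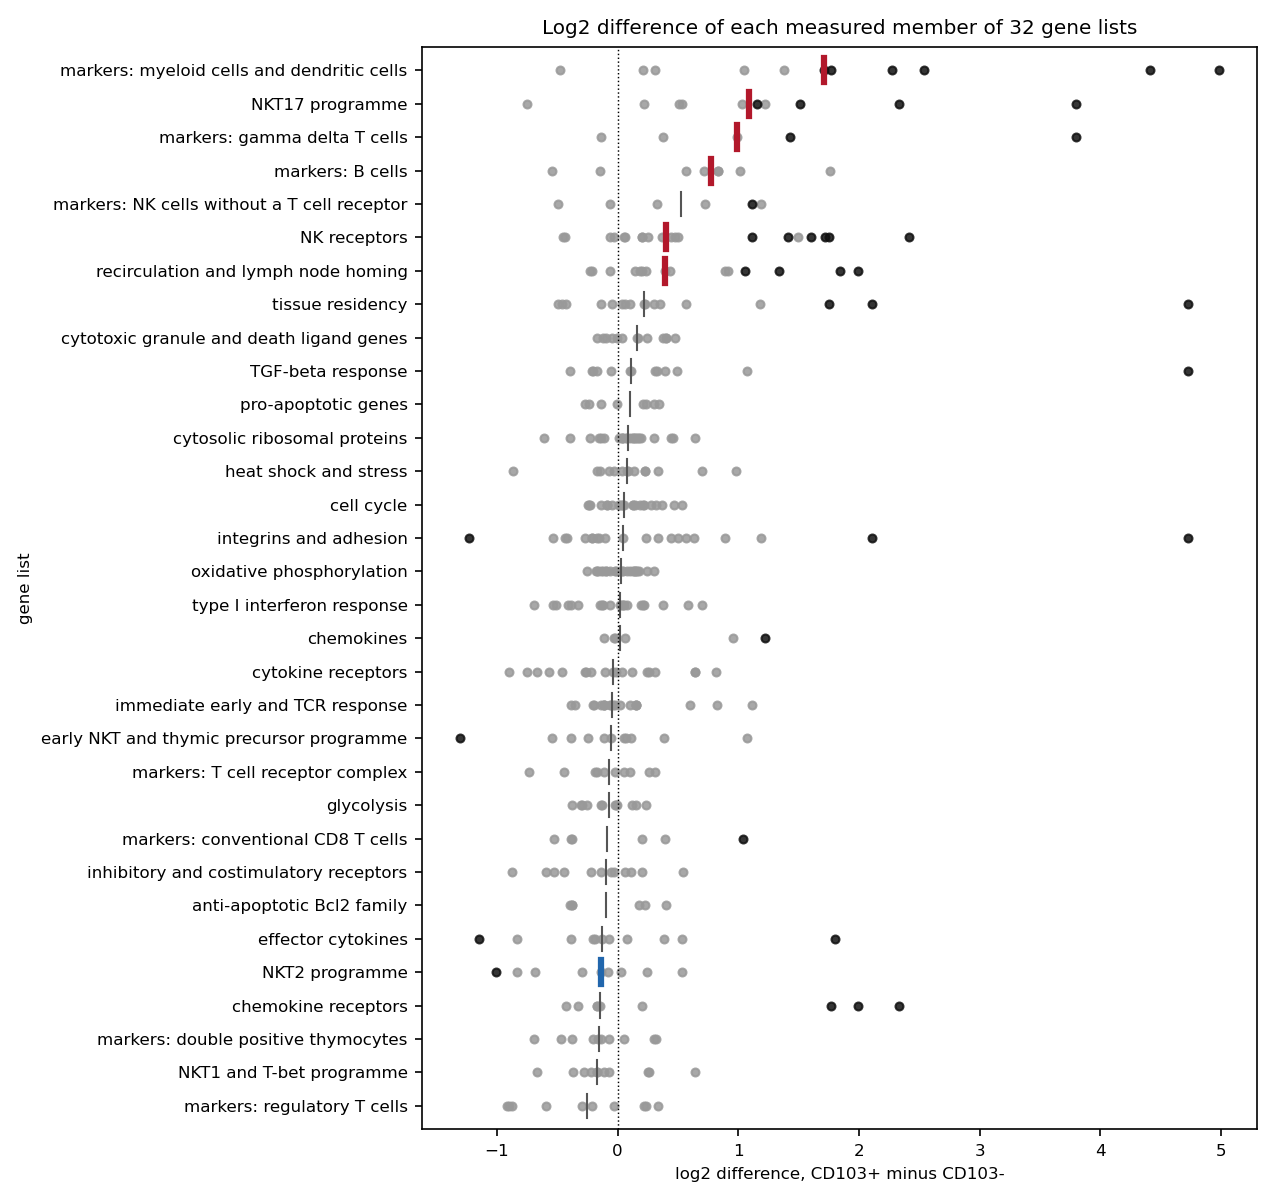
Log2 difference, CD103+ minus CD103-, of each measured member of 32 gene lists, with members past an adjusted p of 0.05 in black and others in grey; thick bars mark the median of the 7 lists past their test (red where the test was positive, blue where negative) and thin bars that of the others. Medians ran from -0.25 for markers of regulatory T cells to 1.71 for markers of myeloid and dendritic cells.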

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

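The bright-array, covariate and centred fits were chosen only after the result was seen, and the cause of each change below was not tested except where stated. Against 206 probes, 162 higher and 44 lower, no background correction gave 315 (111 lower), normexp without detection p-values 94 lower, cyclic loess 87 lower, an offset of 50 86 lower, the strict filter 80 lower, the intensity trend 369 (138 lower), array weights 397 (282 higher, 115 lower) and the authors' values 313 (256 higher), or 94 lower when centred. Median scaling gave 65 higher and 83 lower, and 95 (71 higher, 24 lower) when centred. An adjusted p of 0.01 left 60 (55 higher, 5 lower), by its construction. The replicate block gave 83 (75 higher, 8 lower), the bright arrays alone 135 (105 higher), a fit in which the lone CD103- array is assumed to vary like the CD103+ arrays, and array brightness as a covariate 16 (16 higher, 0 lower), with 1111 probes at an unadjusted p under 0.05. Leaving out 1 array gave 52 to 857 probes, 48 to 610 higher and 4 to 247 lower. All 206 probes kept their sign under the other scalings and with the brightness covariate, except 201 with median scaling and 205 when that was centred; in fits that leave out arrays the separated groups fix the sign. The share of higher probes was 78.6%, against 43.9% with median scaling, 64.8% without background correction, 68.2% with normexp, 64.0% with loess, 68.6% with the offset of 50, 62.6% with the trend, 63.4% in the authors' values when centred and 90.4% with the block. Of 7 lists, an estimated correlation left 0, fry gave 15, all probes of each member 16 and the authors' values when centred 11. The ribosomal protein list, positive and not past, turned negative and passed with median scaling (-0.66), cyclic loess (-0.35), the authors' values (-0.55) and both centred fits (-0.52 and -0.68). The named genes that passed kept the call in 771 of 1028 alternative values, and Itgae, C1qb, Blk and Ifitm2 passed in all 21 alternatives. Lists that passed kept the call in 147 of 168 values, and the NKT2 median turned to 0.03 in the authors' values. Named genes that did not pass did so in 11 of 210 values, and lists that did not pass did so in 43 of 624, beside the 5 reversed. A slide alternative was not run, since the column names give no slides. Signal over background limits folds: 76 of the 162 higher probes were not detected on any CD103- array.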

Other observations

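The gene families of this part were picked after their values were seen, as were the tests on macrophages, dendritic cells, CD8 T cells and gamma delta T cells and those on the dim arrays for gene lists and with these arrays left out; the splits and the share of the difference kept over 857 probes were chosen before.

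All 3 measured Ifitm genes, interferon-inducible membrane proteins, were higher in CD103+ cells under each of 7 scalings, at 2.29 for Ifitm1, 3.53 for Ifitm2 and 1.64 for Ifitm3 on the log2 scale (adjusted p = 0.00675, 6.23e-04 and 0.00579), while 1 further Ifitm1 probe differed in call. The type I interferon response list did not pass (adjusted p = 0.374). All 7 measured Gimap genes, GTPases of lymphocytes, had negative differences under each of 7 scalings (median -0.51), and Gimap7 alone passed. With the dim CD103- arrays left out Gimap9 lay at 0.04, while the other Gimap genes stayed negative. Of 9 measured Klra genes, the Ly49 receptors, the probes annotated to Klra1 (1.41), Klra16 (1.24) and Klra22 (1.20) were higher. Whether each probe reads only the gene it is annotated to was not tested, so these may not be separate genes. Of the 9 differences 8 were positive, 6 of 9 with cyclic loess and, less the median of all probes, 7 of 9 with median scaling and 6 of 9 in the authors' values. With the replicate number as a block Klra1, Klra16 and Klra22 did not pass, at adjusted p of 0.0563 (1.71e-04 to 0.337 over 21 alternatives), 0.0630 (1.81e-04 to 0.185) and 0.0630 (0.00156 to 0.179), and 2 further Klra16 probes and 1 of Klra22 differed in call. Slamf6 and Slamf1 were lower, though not with the replicate block (adjusted p = 0.0546, 0.00404 to 0.218 over 21 alternatives, and 0.0565, 0.00700 to 0.365), and Slamf7 lay at -0.16, turning positive in the authors' values before the median of all probes was taken off and with median scaling after it was. The integrin chain Itgb4, not detected on any CD103- array, was at least 2.28-fold higher (adjusted p = 0.00339). The Actb probes moved apart, from -2.55 to 1.06, with none past the threshold and 0.12 for the brightest.

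Of 206 probes past the threshold, all were counted on a comparison in which 2 of 3 CD103- arrays were dim. The 6 arrays make 10 splits into 3 and 3, and 1 of the 10, the real one, gave 206 probes or more. The highest of the others gave 0, also among the 4 splits that part all arrays of the same replicate number. Either number of splits is too few for a share under 0.05. Dim arrays as the cause of every call are argued against, since 87 of the 206 probes also passed with these arrays left out, a fit on the other 4 arrays that gave 135 probes in all. They may account for others: of 857 probes called without the bright CD103- array 1, the median share of the difference kept against that array was 0.350 (quartiles 0.0451 and 0.733), with 671 of the same sign. With array brightness as a covariate 16 probes passed. Calls lost there do not by themselves show smaller differences, since the SE grew for the genes given below. For the probes that did not pass again the dim arrays and the population both stay open, with a single bright CD103- array to part them.

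Of 32 measured genes on the resident macrophage list 30 had positive differences (93.8%) and 17 were higher in CD103+ cells, while 11 were with the replicate number as a block, 9 without CD103+ array 1 or 3, 5 with median scaling and 4 when that was centred. The list median of 1.42 became 0.69 with median scaling, 0.83 when that was centred and 0.48 without background correction. Dim CD103- arrays as the whole cause are argued against for the list of myeloid markers, which was fixed before: tested with all 11 measured members by camera at the preset correlation, both without the dim arrays and with array brightness as a covariate, its largest adjusted p was 2.96e-09 (0.0429 by fry), and its median of 1.71 became 1.79 and 2.02. With an estimated correlation no list passed in either fit, as with all arrays. On the macrophage list the covariate left 4 genes past the threshold. Without the dim arrays and with the covariate the median was 1.59 and 1.80 after 1.42 and the median SE 0.310 and 0.317 after 0.268. In these fits the median did not shrink while the SE grew. Many of the higher members, such as C1qb and Vcam1, were not detected on any CD103- array. No median with such members at their bound was made for this list. These members passed the detection filter only through the 3 CD103+ arrays, which all but fixed their positive sign. The list was also written after the values were seen, so its share of positive differences is no support for a cause. CD103-bearing dendritic cells stay open: 0 of 10 of their markers with a probe were higher, but 1 alone was detected on all 3 CD103+ arrays, and the MHC class II genes that would go with such cells were positive without passing (0.83 to 1.76). A candidate explanation is macrophages, or pieces of them, among the sorted CD103+ cells. Of the 17 genes 15 lay lower on CD103+ array 2, with Lyz2 (0.34) and Mpeg1 (0.52) as the exceptions. Lyz1, not on this list, also lay higher there, at 12.2 against 11.56 and 11.43. The median of all 17 was -0.78 against 0.16 for 87 other higher genes (difference -0.94). A permutation of genes gave p = 1e-05, the smallest that 100000 permutations give. It takes the genes as independent and concerns a single array. Any genes that vary together would give it, also genes of the NKT cells themselves. The gate on NK1.1 would remove most macrophages. Abundant macrophage genes stood at 0.21 (Cst3), 0.09 (Ctsb) and -0.24 (Psap), where a high signal in both populations would hide a small share. They stood at -0.41 (Ctsd) and 0.31 (Csf1r) where it would not. Expression of these genes by CD103+ NKT cells themselves was not tested and stays open.

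The NKT17 and gamma delta genes Blk, Ccr6, Il17re, Tmem176a and Sox13 were higher in CD103+ cells. Tmem176a passed in 2 of its 20 alternatives. Dim arrays as the whole cause are argued against for both lists, which were fixed before: by camera at the preset correlation, without the dim arrays and with the brightness covariate, the largest adjusted p was 0.00383, and the median of 1.09 of the NKT17 list became 1.03 and 1.05 and that of 0.99 of the gamma delta list 0.66 and 0.76. By fry the NKT17 list did not pass without the dim arrays (0.0615) and the other 3 values did. Of the 5 genes, Blk alone passed with the covariate. Ccr6 was at 1.95 (SE 0.297) with the covariate and 2.20 without the dim arrays, after 2.33 (SE 0.245). Il17re, Tmem176a and Sox13 did not pass with the covariate, at 1.21, 1.48 and 1.67. Their differences were 1.44, 1.17 and 1.41 without the dim arrays after 1.51, 1.15 and 1.43, all against undetected signals, and the SE 0.279, 0.275 and 0.252 after 0.194, 0.191 and 0.175. CD103-bearing CD8 T cells, most of which the gate on NK1.1 and CD44 would remove, stay open: the 3 Cd8b1 probes had a median difference of -0.59 (SD 0.29), but a high signal in both populations (10.49 and 10.87 for the brightest) would hide a small share, and the Cd8a probes were detected on 0 arrays. Gamma delta T cells could be a source: the 3 measured gamma chain variable gene probes had a median of 0.64 (SD 0.21), none past the threshold (smallest adjusted p = 0.235), with 2 of 3 positive with median scaling, or 3 of 3 less the median of all probes. Their median was 0.05 with median scaling, or 0.19 less the median of all probes, and 0.24 without background correction. A larger share of NKT17 cells in the CD103+ population was not tested and stays open. Both populations were sorted as NK1.1+, which limits that explanation to NKT17 cells with NK1.1. Of the 10 measured NKT17 genes 9 had positive differences, while Rora lay at -0.75, and Il17a and Il17f were not measured.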
